A study of Homo sapiens with 9 samples.

How the data were processed

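The values analysed were the deposited RPKM table of the authors, 20874 genes by 9 libraries, with no column left out. Per the labels' protocols, polyA RNA was made into unstranded libraries and sequenced as single-end reads of 40 bp. Per the submitters' processing notes, reads were processed with bcl2fastq 1 and TopHat2 2.0.8b against hg19, and Partek gave the RPKM values per gene. How reads that match several genes were divided is not given in the sources used here. Values were checked to be fractions of reads that behave as RPKM: 79.5% to 87.3% of low values of miRNA genes lay on whole steps within a tolerance of 0.03, and these steps gave the estimated depth. Gene names were matched to a reference for GRCh38, used for names and miRNA gene lengths only. Of the names 18693 were current symbols, 1552 older symbols and 629 were not found, and 785 had a hyphen restored where the table holds a dot. The reference and the table are on different builds, so positions of genes are not printed. Raw reads were not used here.

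The analysis ran in R 4.3.3 with limma 3.58.1, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Genes with RPKM 1 or more in at least 3 of 9 libraries were kept, 12017 genes, and 8857 were left out. Named genes below the filter were tested in a fit without it. Values entered as log2(RPKM + 0.5), and all 9 libraries were fitted together with a mean per group, moderated with an intensity trend (prior degrees of freedom 5.52, residual 6). The 3 comparisons were siSGK3 against siNC, siAREG against siNC and siAREG against siSGK3. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05 with no least fold change. The filter, scale, model, gene lists, named-gene rule and alternative settings were chosen before the data were examined. The liver marker list, the term for liver transcripts, the fit without short RNA genes and 4 further gene lists were added afterwards.

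The 22 gene lists were estrogen receptor targets, luminal identity genes, markers of basal, mesenchymal, stromal and leukocyte cells, ERBB ligands with receptors and sheddases, ERK pathway outputs, ER chaperones with the unfolded protein response, ATF4 targets, ER calcium genes, G2 and mitosis genes, S phase genes, cholesterol synthesis genes, type I interferon response genes, p53 targets, AKT and SGK kinases with partners, FOXO targets, the BCL2 family, hypoxia and glycolysis genes, androgen receptor targets, lysosome and autophagy genes, replication-dependent histone genes, ribosomal protein genes and small RNA pathway genes. They were written from general knowledge of these pathways. Lists were tested against all other genes with camera at a preset correlation of 0.01, adjusted over the 22 lists. Camera with an estimated correlation was tried as an alternative. Fry was run as well and answers another question, since it tests whether a list moves at all and not whether it differs from other genes.

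Genes named were the targets with ESR1 and CYP19A1, the 10 largest rises and falls of each knockdown against siNC among called genes whose 3 libraries all lay on 1 side of the other 3, the 5 each way between the knockdowns, the 5 each way called in both, the 5 most opposite ones, and up to 4 members of each list. Other alternatives changed the filter, the added constant, the scaling and normalization, and the fit, and left out each library in turn. Same-numbered libraries were checked for pairing: deviations from group means correlated at -0.0799 to 0.0894, with 0 of 9 pairs above 0.1, so numbers were not used to pair. Overlap between the knockdowns was compared with 100 simulations that share the controls.

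The method was tested on simulated data with the same group sizes, 50 changed genes per size of effect. At a log2 change of 0.25 it found 60% of genes in siSGK3, 62% in siAREG and 60% between them; at 0.5 it found 92%, 92% and 98%. False calls were 6, 11 and 10 of 11817 unchanged genes, which is 3.31%, 5.88% and 5.29% of all calls. Camera found the 1 shifted list and 0 others. The simulated genes varied independently and the simulated lists were random. False list calls that arise from correlation between genes were therefore not tested.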

Results

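The series asked which transcripts change in breast cancer cells that resist letrozole when amphiregulin (AREG) or serum/glucocorticoid-regulated kinase 3 (SGK3) is knocked down. AREG is a ligand of the epidermal growth factor receptor, and SGK3 is a serine/threonine kinase related to AKT that is recruited to endosomes. The cells were MCF7aro, an MCF-7 line that expresses aromatase (CYP19A1, the enzyme that makes estrogens from androgens), kept for more than 6 months in the aromatase inhibitor letrozole. Each of 3 groups held 3 libraries, each transfected at 30 nM for 48 h. They were a negative control siRNA (siNC), a pool of 3 siRNAs against SGK3 (siSGK3) and a pool of 3 siRNAs against AREG (siAREG). The control siRNA came from a different supplier than both pools, so supplier cannot be told apart from knockdown in comparisons with siNC. The labels give 200 nM letrozole, 1 nM testosterone and 10% fetal bovine serum marked CD for all libraries. RPKM values of 20874 genes were given per library, and 12017 genes passed the filter of RPKM 1 in at least 3 libraries. Depth estimated from the steps of the lowest values was 29.5 ± 0.937 M reads in siNC, 34.2 ± 1.30 M in siSGK3 and 32.5 ± 1.66 M in siAREG (SD, n = 3), so RPKM 1 stands for 28.6 to 35.7 reads per kb of gene. Values below are mean RPKM ± SD of n = 3 libraries, or log2 fold change ± SE on the log2(RPKM + 0.5) scale, which understates the change of low genes. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

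Each pool lowered its own target. SGK3 was 12.2 ± 0.896 RPKM in siNC and 3.42 ± 0.0772 in siSGK3, which is 28.0% of the control (log2 fold change -1.69 ± 0.06, limma adjusted p = 8.95e-10, lower in 3 of 3 libraries). AREG was 83.0 ± 2.48 RPKM in siNC and 22.1 ± 4.04 in siAREG, or 26.6% of the control (log2 fold change -1.90 ± 0.09, limma adjusted p = 4.00e-09, lower in 3 of 3 libraries). The siSGK3 pool left AREG at 79.6 ± 1.55 RPKM (log2 fold change -0.06 ± 0.09, limma adjusted p = 0.604). SGK3 was also lower in siAREG than in siNC, at 7.12 ± 0.467 RPKM or 58.4% of the control (log2 fold change -0.73 ± 0.06, limma adjusted p = 3.21e-07). The readthrough gene C8orf44-SGK3, which shares exons with SGK3 and lay below the filter, was 0.667 ± 0.134 RPKM in siNC, 0.154 ± 0.0589 in siSGK3 and 0.633 ± 0.122 in siAREG. In a fit without the filter its fall passed in siSGK3 (log2 fold change -0.83 ± 0.11, limma adjusted p = 0.000753) and its change in siAREG did not (-0.04 ± 0.11, 0.821). How reads were divided between SGK3 and the readthrough gene is not given in the sources used here. ESR1, which encodes the estrogen receptor alpha, fell in both knockdowns, from 41.0 ± 1.37 RPKM to 24.5 ± 1.02 in siSGK3 (log2 fold change -0.73 ± 0.04) and 18.4 ± 0.515 in siAREG (-1.14 ± 0.04). CYP19A1 was 103 ± 0.839, 111 ± 0.473 and 106 ± 0.512 RPKM in siNC, siSGK3 and siAREG. That small rise passed the test in siSGK3 (log2 fold change 0.11 ± 0.02, limma adjusted p = 0.00114); in siAREG it did not (0.04 ± 0.02, 0.112), and there it passed without the filter (0.0299) and after quantile normalization (0.000404). AREGB, the annotated copy of AREG, was not analysed here.

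**Figure D1:**
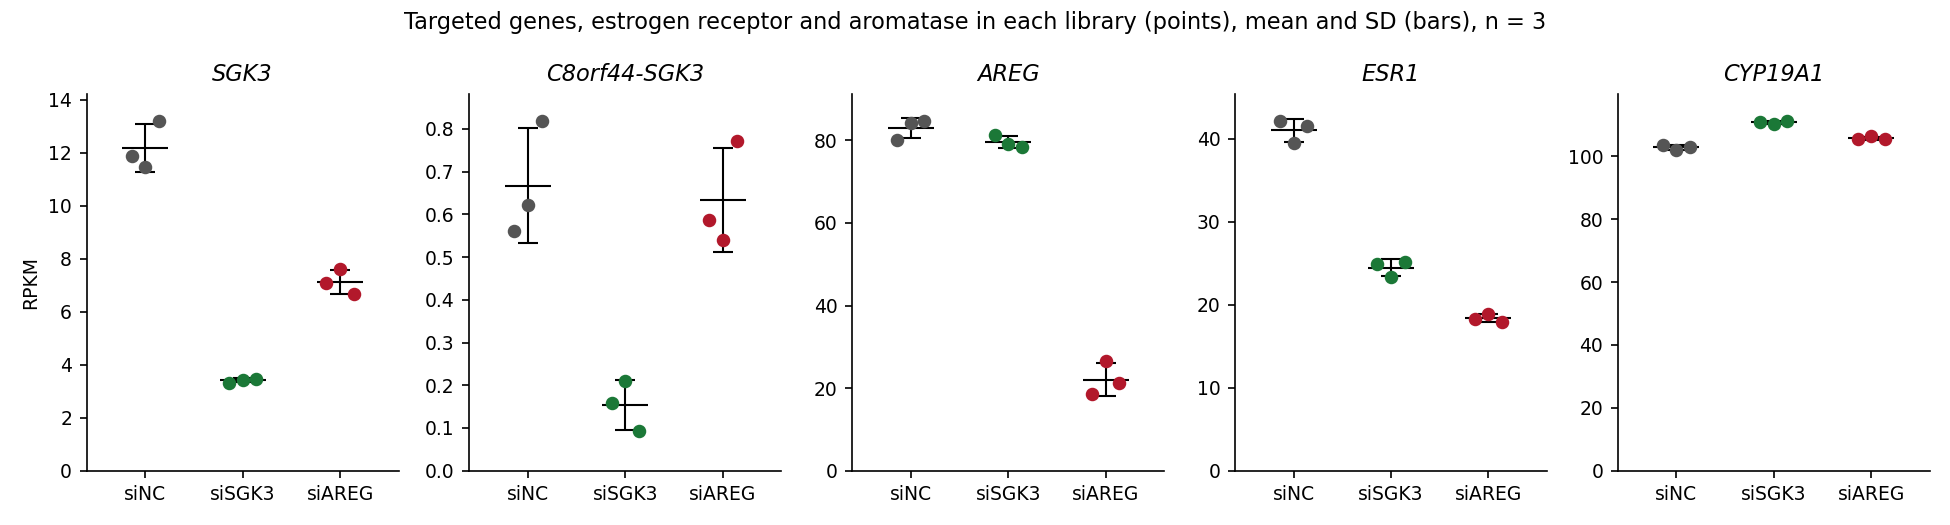
RPKM (vertical axes, from 0) of SGK3, C8orf44-SGK3, AREG, ESR1 and CYP19A1 in the siNC, siSGK3 and siAREG libraries (points), with the mean and SD of n = 3 as bars. SGK3 is lowest in siSGK3 at 3.42 and intermediate in siAREG at 7.12, AREG falls in siAREG alone to 22.1, and ESR1 is lower in both knockdowns than in siNC.

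Transcripts of hepatocyte secretory genes, which are made mainly in the liver, divided the libraries in a way that the groups do not. ALB, which encodes serum albumin, was 1.27 ± 0.190 RPKM in siAREG, 1.09 in siSGK3 replicate 3, 0.0446 on average in siSGK3 replicates 1 and 2, and 0.00992 ± 0.00860 in siNC. Across these 4 libraries (siSGK3 replicate 3 and siAREG replicates 1 to 3) RBP4 averaged 1.60 ± 0.108 RPKM, APOA2 1.34 ± 0.282 and TF 0.975 ± 0.0769 (SD over 4 libraries). Of 38 liver marker genes with a value, which include enzymes and receptors of hepatocytes, 18 lay higher in all 4 libraries than in all 5 others. In the 5 other libraries RBP4 and APOA2 were listed at 0, and TF averaged 0.0654 ± 0.0531. The 4 libraries carry adjoining numbers in the names of their columns. This split crosses the comparisons, so each is also given within it where that is possible. Leaving out siSGK3 replicate 3 puts siSGK3 and siNC on the side of the split with low levels; siAREG and siNC lie wholly on opposite sides, so a model term for the 4 libraries then rests on siSGK3 replicate 3 against replicates 1 and 2.

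**Figure D2:**
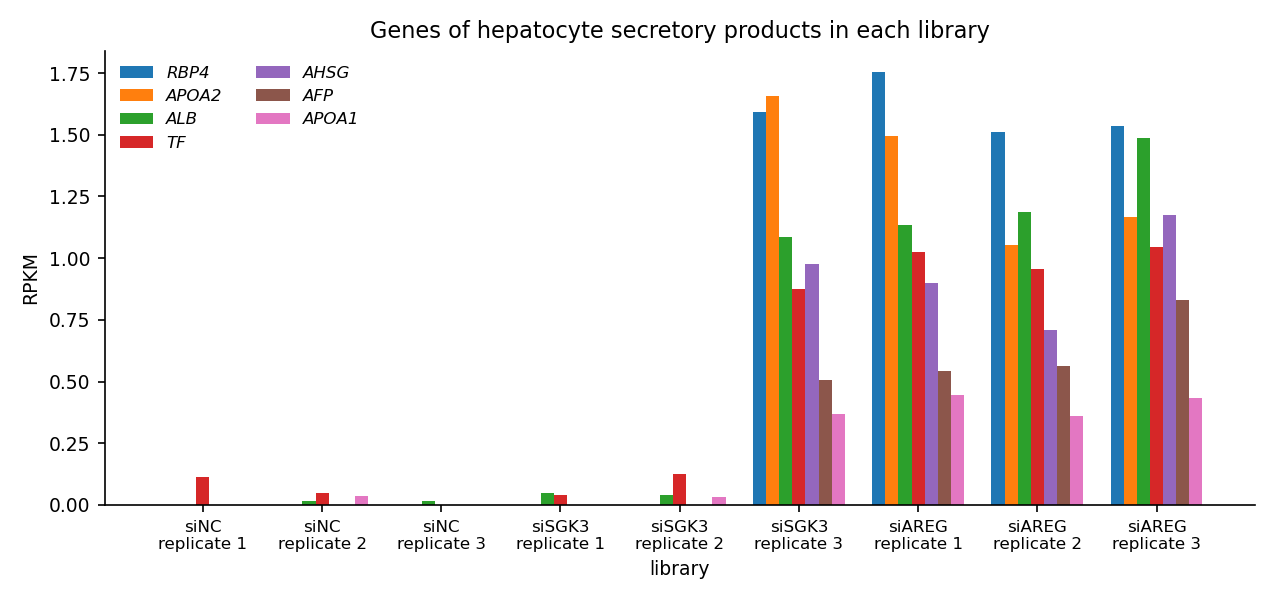
RPKM (vertical axis, from 0) of 7 genes of hepatocyte secretory products (colours) in each of the 9 libraries. siSGK3 replicate 3 and the 3 siAREG libraries carry all 7, with ALB between 1.09 and 1.49 RPKM, whereas the 3 siNC libraries and siSGK3 replicates 1 and 2 lie near 0.

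Against siNC, the siSGK3 libraries were higher in genes of the endoplasmic reticulum (ER) stress, integrated stress and interferon responses and lower in genes of the cell cycle. Those lists were called by camera at the preset correlation and none at an estimated correlation (lowest adjusted p = 0.113). KLHDC7B showed the greatest rise, from 0.529 ± 0.0652 to 7.02 ± 0.503 RPKM (log2 fold change 2.87 ± 0.07). FAM129A, a stress-induced regulator of translation, rose by 2.82 ± 0.06, and BHLHA15, a transcription factor of secretory cells, by 2.61 ± 0.08. HERPUD1, a part of the machinery that removes misfolded ER proteins, rose from 14.6 ± 0.251 to 69.7 ± 2.95 RPKM (2.21 ± 0.04), and DDIT3, which encodes the stress transcription factor CHOP, from 28.1 ± 0.981 to 116 ± 2.67 (2.03 ± 0.05). The other large rises were LOC100287177 (2.31 ± 0.12), the histone gene HIST1H2BN (2.06 ± 0.10), INHBE (2.05 ± 0.08), RGS16 (2.03 ± 0.04) and S100P (1.99 ± 0.09). Falls were smaller. CAV1, which encodes caveolin-1, fell from 61.4 ± 2.81 to 22.8 ± 0.889 RPKM (-1.41 ± 0.04), PCP4 fell to 7.87 ± 0.445 from 19.6 ± 1.48 (-1.26 ± 0.06). SGK1, the kinase closest in name and family to SGK3, fell from 3.05 ± 0.355 to 1.07 ± 0.0873 (-1.18 ± 0.08). STRADB (-1.20 ± 0.07), IGFBP3 (-1.11 ± 0.05), SCML2 (-1.08 ± 0.06) and UGT2B17 (-1.06 ± 0.10) also fell; UGT2B17 has close paralogs that may share its reads. Of the short RNA genes, SNORD99 fell by 1.26 (SE 0.27), MIR3176 by 1.51 (SE 0.48) and MIR429 by 0.99 (SE 0.33), from few reads each. The MIR429 call ended without siSGK3 replicate 1 (-0.56, limma adjusted p = 0.0681) and that of MIR3176 without siSGK3 replicate 2 (-0.96, 0.0875) or siNC replicate 1 (-1.25, 0.0663). Both calls also ended without the filter (0.0907 for MIR429 and 0.0848 for MIR3176).

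In all, 3367 genes were higher and 3727 lower in siSGK3 than in siNC (limma with an intensity trend, two-sided, Benjamini-Hochberg adjusted p under 0.05), 59.0% of the 12017 tested. The 3 siSGK3 libraries all lay on 1 side of the 3 siNC libraries in 63.6% of genes, against 10% by chance. Most changes were small: 594 of the higher and 115 of the lower genes changed by 1.5-fold or more. More genes were lower than higher, and this turned without the filter (3684 higher and 3558 lower) and without siSGK3 replicate 2 (3444 higher and 3379 lower). Without siSGK3 replicate 3, the siSGK3 library that carried most of the liver transcripts, 3005 genes were higher and 3483 lower. That fit still held the siAREG libraries.

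Of the 22 gene lists, 8 were called by camera in siSGK3 against siNC. ER chaperone and unfolded protein response genes moved together: 24 rose and 1 fell of 25 measured (median log2 fold change 1.00, camera adjusted p = 3.69e-14; 0.199 with an estimated correlation). HSPA5, which encodes the ER chaperone BiP, rose from 172 ± 4.16 to 465 ± 19.7 RPKM (1.43 ± 0.03), DNAJB9 rose by 1.92 ± 0.03 and HYOU1 by 1.48 ± 0.04; XBP1 was the member that fell (-0.19 ± 0.02). Among ATF4 and integrated stress response targets 24 rose and 1 fell of 25 measured (median 0.80, camera adjusted p = 1.13e-14; 0.188 with an estimated correlation). Asparagine synthetase, ASNS, rose from 48.6 ± 1.06 to 132 ± 4.49 RPKM (1.43 ± 0.03), DDIT4 by 1.43 ± 0.04 and the tryptophanyl-tRNA synthetase gene WARS by 1.29 ± 0.03. All 25 measured type I interferon response genes rose (median 0.89, camera adjusted p = 2.05e-12; 0.306 with an estimated correlation). Examples were OAS1 at 29.8 ± 1.45 and 68.1 ± 3.66 RPKM (1.18 ± 0.05), IFI44 (1.02 ± 0.06), and the sensors of double-stranded RNA IFIH1 (1.11 ± 0.06) and DDX58 (0.96 ± 0.06). These counts were the same when adjusted over the list alone.

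Proliferation genes went down. All 26 G2 and mitosis genes fell (median -0.45, camera adjusted p = 1.21e-10; 0.132 with an estimated correlation), with CCNB1 at 95.7 ± 1.12 and 69.3 ± 0.382 RPKM (-0.46 ± 0.02), AURKA at -0.47 ± 0.02 and MYBL2 at -0.55 ± 0.03. Of 25 S phase and DNA replication genes 24 fell (median -0.36, camera adjusted p = 1.17e-09; 0.113 with an estimated correlation), among them TYMS (-0.54 ± 0.03), RRM2 (-0.69 ± 0.04) and PCNA (-0.64 ± 0.04), while the origin licensing factor CDC6 rose (0.37 ± 0.04). The counts for both lists were the same when adjusted over the list alone. Estrogen receptor target genes fell on balance: 4 rose and 22 fell of 34 measured, or 4 and 23 adjusted over the list alone (median -0.23, camera adjusted p = 0.000639; 0.270 with an estimated correlation). CCND1, which encodes cyclin D1, fell from 199.9 ± 1.73 to 126 ± 5.11 RPKM (-0.67 ± 0.03), PKIB fell by 0.67 ± 0.03 and TPD52L1 fell by 0.48 ± 0.03. AGR2, a protein disulfide isomerase, went the other way, from 100.2 ± 1.63 to 231 ± 9.23 (1.20 ± 0.04).

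Outputs of the ERK pathway rose in 13 and fell in 2 of 20 genes, or 13 and 3 adjusted over the list alone (median 0.28, camera adjusted p = 0.0191; 0.673 with an estimated correlation). EGR1 rose (0.75 ± 0.04) and so did ETV5 (0.46 ± 0.04), whereas CCND1 and EPHA4 (-0.48 ± 0.04) fell. The list was not called among genes at RPKM 5 or more (camera adjusted p = 0.136). Cholesterol synthesis genes rose in 14 and fell in 6 of 24, or 16 and 6 adjusted over the list alone (median 0.13, camera adjusted p = 0.0210; 0.673 with an estimated correlation), with STARD4 at 1.27 ± 0.05, MSMO1 at 0.49 ± 0.03 and HMGCS1 at 0.47 ± 0.04. The other 14 lists were not called, and single members still changed. In the AKT and SGK list (4 rose and 5 fell of 13 measured, camera adjusted p = 0.551) NDRG1 rose by 1.05 ± 0.06 and FOXO3 by 0.77 ± 0.06. Among FOXO targets (8 rose and 3 fell of 18 measured, 0.143) GADD45A rose by 1.11 ± 0.03, and in the BCL2 family (6 rose and 3 fell of 14 measured, 0.454) the proapoptotic genes HRK (1.65 ± 0.09), PMAIP1 (0.84 ± 0.08) and BBC3 (0.71 ± 0.07) rose. Of p53 targets 8 rose and 8 fell (0.775; median -0.04 and mean 0.10), with GDF15 up by 1.67 ± 0.04. Of lysosome and autophagy genes 9 rose and 8 fell of 21 measured (0.539), led by WIPI1 (1.70 ± 0.04) and MAP1LC3B (1.21 ± 0.04).

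In the ER calcium list 10 rose and 3 fell of 17 measured (camera adjusted p = 0.0627), SELK by 1.07 ± 0.04. That list passed among genes at RPKM 5 or more (0.0344), after quantile normalization (0.0472), with array weights (0.0399) and without siSGK3 replicate 2 (0.0272). Of hypoxia and glycolysis genes 4 rose and 12 fell of 22 measured (0.324): VEGFA rose (1.12 ± 0.04) and LDHA fell (-0.31 ± 0.02). Of luminal identity genes 3 rose and 8 fell of 21 measured (0.372), with KRT19 down (-0.36 ± 0.03) and MUC1 up (1.23 ± 0.10). Of ERBB ligands, receptors and sheddases 4 rose and 2 fell of 12 measured (0.0849), HBEGF by 0.94 ± 0.08 and the feedback inhibitor ERRFI1 by 0.59 ± 0.04. Markers of basal, mesenchymal, stromal and leukocyte cells were mostly too low to test, and of the 6 measured 1 rose, COL1A1 (0.66 ± 0.07; list 0.533). Androgen receptor targets rose in 6 and fell in 6 of 12 (0.971; median 0.03, mean -0.01), and small RNA pathway genes rose in 5 and fell in 4 of 15 (0.775), where the kinase gene EIF2AK2 rose (0.41 ± 0.04) and DICER1 fell (-0.59 ± 0.05). Ribosomal protein genes had 1 rise and 16 falls of 38 (median -0.06, 0.0682). They passed without the filter (0.00261), with array weights (0.0399) and without siNC replicate 3 (0.0368), siSGK3 replicate 1 (0.0377) or siSGK3 replicate 2 (0.0272). Replication-dependent histone genes, a sign of RNA selection, rose and fell in 4 and 6 of 12 (0.955; median -0.13, tested upward). Adjusted over the list alone the counts became 3 and 7 for the luminal list, 4 and 1 for the ERBB list and 1 and 14 for the ribosomal list, and were unchanged for the other lists not called.

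The siAREG libraries differed from siNC in many of the same genes, again with no list called at an estimated correlation (lowest camera adjusted p = 0.118). BHLHA15 rose from 1.21 ± 0.157 to 20.7 ± 0.495 RPKM (log2 fold change 3.63 ± 0.08), KLHDC7B to 11.4 ± 0.699 (3.53 ± 0.07) and FAM129A to 17.0 ± 0.363 (3.40 ± 0.06). The ER cochaperone gene DNAJB9 rose from 20.2 ± 0.344 to 133 ± 4.88 RPKM (2.69 ± 0.03) and HERPUD1 to 96.6 ± 2.91 (2.68 ± 0.04). BATF2, an interferon-induced transcription factor, rose by 2.77 ± 0.12 and LCN2, which encodes the iron-siderophore carrier lipocalin-2, by 2.65 ± 0.09; LOC100287177 (2.92 ± 0.12), HIST1H2BN (2.70 ± 0.10) and RGS16 (2.52 ± 0.04) complete the 10 largest rises. CAV1 fell from 61.4 ± 2.81 to 15.4 ± 0.323 RPKM (-1.96 ± 0.04), PCP4 to 4.90 ± 0.252 (-1.89 ± 0.06) and GJA1, which encodes the gap junction protein connexin 43, from 65.3 ± 3.20 to 19.8 ± 0.456 (-1.69 ± 0.04). IGFBP3 (-1.42 ± 0.05), SYTL5 (-1.27 ± 0.06) and the androgen-conjugating enzymes UGT2B17 (-1.30 ± 0.10) and UGT2B15 (-1.21 ± 0.13), paralogs that may share reads, fell as well. ZBTB8OS fell in siAREG from 17.0 ± 0.770 to 6.61 ± 0.160 RPKM (-1.30 ± 0.07) and was 16.5 ± 1.77 in siSGK3 (-0.05 ± 0.07, limma adjusted p = 0.537). The short RNA genes SNORD34 (-1.73 ± 0.30), which lies inside another gene, and MIR4461 (-1.40 ± 0.26) fell from few reads. The MIR4461 call ended with a term for liver transcripts (-1.22, limma adjusted p = 0.0600).

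By limma, 4490 genes were higher and 4195 lower in siAREG than in siNC, 72.3% of those tested, and 1228 and 444 of them changed by 1.5-fold or more. The 3 siAREG libraries lay on 1 side of the 3 siNC libraries in 75.7% of genes, against 10% by chance. All 3 siAREG libraries and none of the siNC libraries had ALB at RPKM 0.5 or more, the level that defined the split by liver transcripts. With a term for that split 3029 genes were higher and 3111 lower, no called list lost its call, and the luminal identity list passed as well (camera adjusted p = 0.0445). More genes were higher than lower, and this turned with that term, after quantile normalization (3865 higher and 4929 lower) and among genes at RPKM 5 or more (3165 higher and 3367 lower).

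Camera called 7 lists in siAREG against siNC. In the ER chaperone list 24 rose and 1 fell of 25 measured (median 1.40, camera adjusted p = 4.37e-11; 0.252 with an estimated correlation), with HSPA5 at 582 ± 17.0 RPKM (1.76 ± 0.03) and HYOU1 at 299.9 ± 10.7 (1.96 ± 0.04), and again XBP1 as the member that fell (-0.29 ± 0.02). Of ATF4 targets 24 rose and 1 fell of 25 measured (median 1.16, camera adjusted p = 3.95e-11; 0.243 with an estimated correlation), with ASNS (1.76 ± 0.03), WARS (1.72 ± 0.03), DDIT4 (1.62 ± 0.04) and DDIT3 (2.41 ± 0.05) among the rises. All 25 interferon response genes rose (median 1.45, camera adjusted p = 3.95e-11; 0.351 with an estimated correlation), OAS1 to 101 ± 6.98 RPKM (1.74 ± 0.05), IFIT2 by 1.78 ± 0.06, IFIH1 by 1.82 ± 0.06 and OASL by 1.82 ± 0.07. All 26 G2 and mitosis genes fell (median -0.58, camera adjusted p = 3.22e-10; 0.140 with an estimated correlation), CCNB1 to 60.3 ± 1.18 RPKM (-0.66 ± 0.02) and CCNA2 to 16.6 ± 0.235 (-0.86 ± 0.04). Of S phase genes 24 of 25 fell (median -0.54, camera adjusted p = 1.74e-09; 0.118 with an estimated correlation), including TYMS (-0.80 ± 0.03), RRM2 (-1.01 ± 0.04) and MCM2 (-0.63 ± 0.03), and CDC6 rose (0.72 ± 0.04). These counts were the same when adjusted over the list alone.

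Estrogen receptor targets fell on balance: 4 rose and 27 fell of 34 measured, the same adjusted over the list alone (median -0.51, camera adjusted p = 7.36e-07; 0.140 with an estimated correlation). PDZK1 fell from 28.8 ± 0.361 to 12.3 ± 0.326 RPKM (-1.19 ± 0.03), CCND1 to 101 ± 2.57 (-0.98 ± 0.03) and PKIB to 47.7 ± 1.70 (-1.02 ± 0.03), while AGR2 rose to 268 ± 12.6 (1.42 ± 0.04). Ribosomal protein genes fell in 28 of 38 (28 lower and 1 higher adjusted over the list alone; median -0.14, camera adjusted p = 0.000127; 0.745 with an estimated correlation), with RPL7 at -0.29 ± 0.02 and RPS4X at -0.33 ± 0.03. After quantile normalization the list was tested upward and not called (camera adjusted p = 0.347), and RPL7 stood at -0.09. The other 15 lists were not called (camera adjusted p from 0.0876 for luminal identity genes, which passed without the filter at 0.00838, to 0.978 for lysosome genes). The ERK list, called in siSGK3, had 12 higher and 3 lower genes here (median 0.21, camera adjusted p = 0.119), and the cholesterol list 10 and 7 (0.713). Within lists not called, KRT8 (-0.41 ± 0.03), KRT19 (-0.62 ± 0.03) and GATA3 (-0.44 ± 0.03) of the luminal genes fell. Of the other lists HRK (2.13 ± 0.09), PMAIP1 (1.47 ± 0.08), GADD45A (1.57 ± 0.03), GDF15 (2.09 ± 0.04), WIPI1 (2.36 ± 0.04), VEGFA (1.34 ± 0.04), NDRG1 (1.23 ± 0.06) and COL1A1 (1.17 ± 0.07) rose. LDHA (-0.54 ± 0.02) of the hypoxia list, BID (-0.47 ± 0.04) of the BCL2 list and AKT1 (-0.43 ± 0.03) of the AKT and SGK list fell, and more hypoxia genes fell than rose. The tested direction and the median differed in sign for the lysosome list (median -0.01, mean 0.16), and the median (-0.06) and mean (0.06) did for the AKT and SGK list. Genes higher and lower, with the camera adjusted p, numbered 4 and 12 of 21 for the luminal list (0.0876), 2 and 2 of 6 for the basal and stromal list (0.908) and 6 and 1 of 12 for the ERBB list (0.201). There were 10 and 4 of 17 for the ER calcium list (0.201), 9 and 8 of 21 for the p53 list (0.494) and 4 and 4 of 13 for the AKT and SGK list (0.908). There were 10 and 3 of 18 for the FOXO list (0.257), 6 and 3 of 14 for the BCL2 list (0.439) and 7 and 13 of 22 for the hypoxia list (0.201). There were 5 and 6 of 12 for the androgen receptor list (0.635), 10 and 9 of 21 for the lysosome list (0.978), 5 and 5 of 12 for the histone list (0.908) and 6 and 4 of 15 for the small RNA pathway list (0.703). Adjusted over the list alone the counts became 5 and 6 for the histone list, and were unchanged for the other lists not called.

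**Figure D3:**
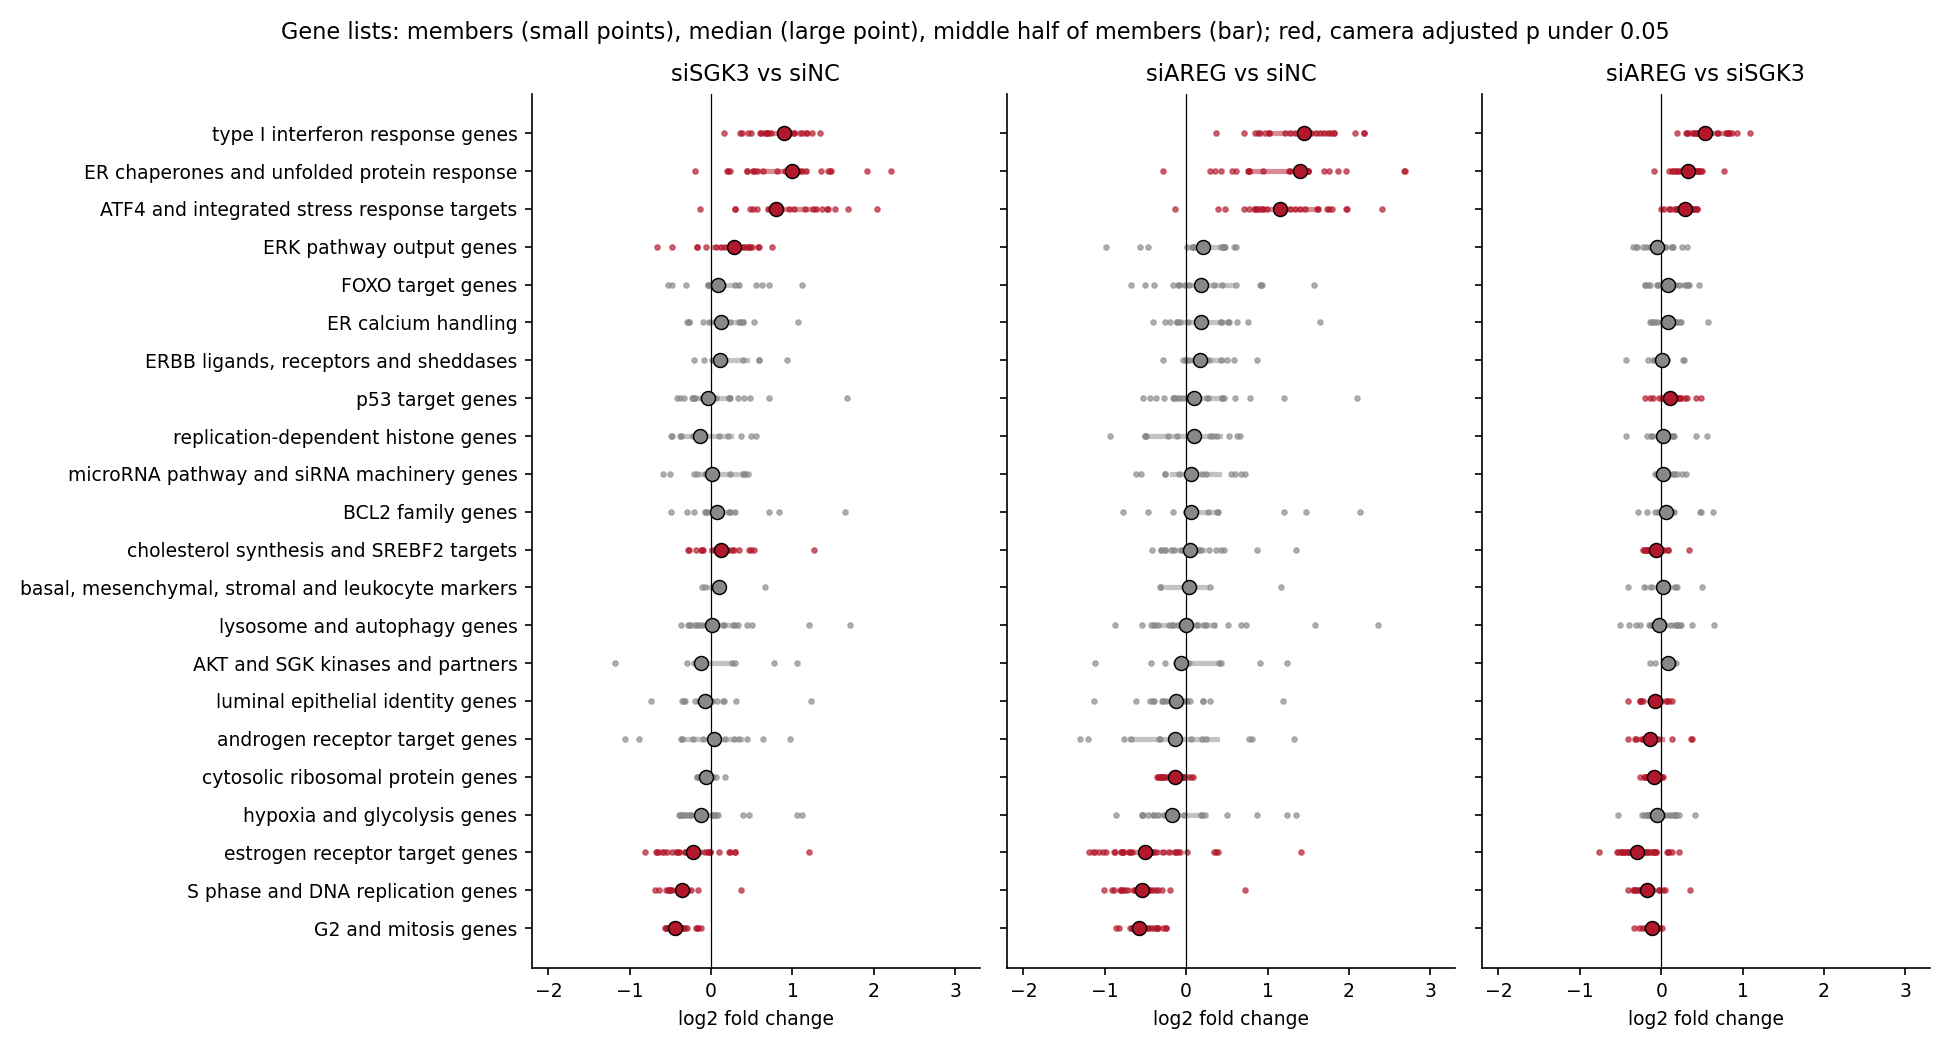
log2 fold change (horizontal axes) of the members of 22 gene lists (rows; small points) with the median (large point) and the middle range of the members (bar) in siSGK3 against siNC, siAREG against siNC and siAREG against siSGK3; red marks lists with a camera adjusted p under 0.05 at the preset correlation. Interferon, ER chaperone and ATF4 lists lie to the right, with medians of 1.45, 1.40 and 1.16 in siAREG, and the G2, S phase and estrogen receptor target lists lie to the left.

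The responses to the pools overlapped closely. Of the genes called in both, 6481 changed in the same direction (3172 higher and 3309 lower) and 29 in opposite directions. The opposite genes numbered 13 with a term for liver transcripts and 43 after quantile normalization. KLHDC7B, BHLHA15, FAM129A, LOC100287177 and HERPUD1 had the largest mean rises, and CAV1, PCP4, GJA1, IGFBP3 and UGT2B17 the largest mean falls besides SGK3 itself (GJA1 -0.97 ± 0.04 in siSGK3). Among opposite genes, ARL1, a small GTPase of the trans-Golgi, was 19.5 ± 0.555 RPKM in siNC, 16.8 ± 0.428 in siSGK3 (-0.21 ± 0.03) and 28.2 ± 0.505 in siAREG (0.53 ± 0.03). ELOVL7, a fatty acid elongase, changed by -0.24 ± 0.05 and 0.44 ± 0.05, TMEM167B by -0.09 ± 0.04 and 0.51 ± 0.04, ZBTB41 by -0.18 ± 0.05 and 0.36 ± 0.05, and ZNF746 by -0.39 ± 0.05 and 0.16 ± 0.05. The TMEM167B call in siSGK3 ended without any single siNC library, without siSGK3 replicate 1 or 3 and without siAREG replicate 1 (-0.07 without siSGK3 replicate 3, limma adjusted p = 0.168), and that of ZNF746 in siAREG without siAREG replicate 2 (0.12, 0.0721). With a term for liver transcripts ZNF746 in siAREG stood at 0.01 (limma adjusted p = 0.920), and after quantile normalization at 0.10 (0.0615). TMEM167B in siSGK3 lost its call in both of these as well (0.170 and 0.102) and without the filter (0.0718).

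Both comparisons use the same 3 siNC libraries, so some overlap arises with no effect. Across genes, which are not independent replicates, the fold changes correlated at Pearson r = 0.930. The value was 0.494 (range 0.398 to 0.562) in 100 simulations of unchanged groups that shared controls, all drawn around the siNC means. Simulated genes varied independently, so that range leaves out correlation between genes. The covariance was 0.133 against a simulated 0.00265, a difference of 0.131, and 88.3% of genes had the same sign against 66.7%. The simulations called 0.04 genes in both on average. Independent lists of the observed sizes would share 1258 higher and 1301 lower genes. The 3 controls are too few to split, so part of the excess of shared calls over those numbers may come from sharing them. The shared spread between siNC libraries adds the same covariance with or without effects, so the difference in covariance does not come from that spread. A deviation common to all 3 siNC libraries would also add covariance, and the simulations leave it out. In 85.8% of the same-direction genes the change was larger in siAREG, with a median ratio of 1.45.

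**Figure D4:**
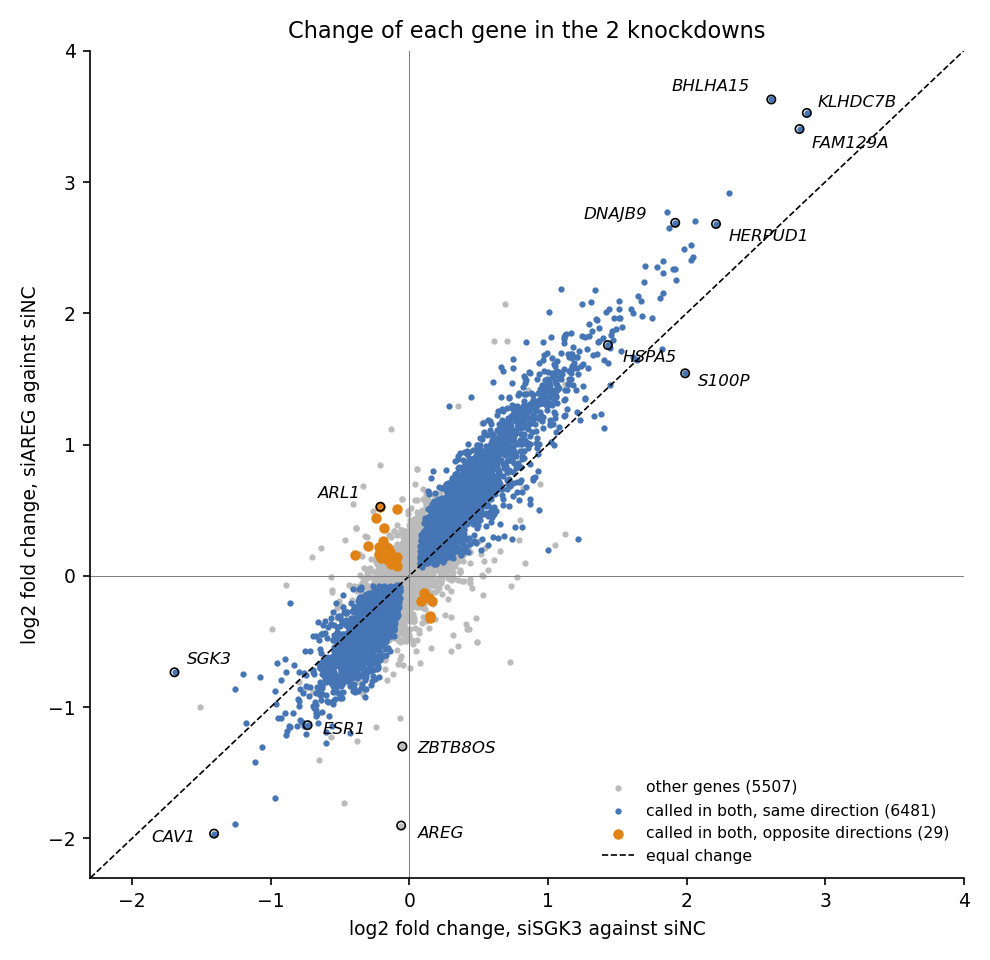
log2 fold change of each of 12017 genes in siSGK3 (horizontal axis) and siAREG (vertical axis) against siNC; blue marks the 6481 genes called in both in the same direction, orange the 29 called in opposite directions and grey the rest, and the dashed line marks equal change. Most blue genes lie further from 0 in siAREG, SGK3 lies at -1.69 and -0.73, and AREG and ZBTB8OS lie near 0 in siSGK3.

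Set against each other, the siAREG libraries were higher than the siSGK3 libraries in 3000 genes and lower in 1958 by limma, 41.3% of those tested. Few changes were large: 81 and 26 reached 1.5-fold. Interferon lambda 3, IFNL3, was 0.630 ± 0.0639 RPKM in siSGK3 and 2.23 ± 0.639 in siAREG (log2 fold change 1.25 ± 0.15); its near-identical neighbour IFNL2 may share its reads. XAF1, an interferon-induced apoptosis regulator, rose from 3.18 ± 0.390 to 7.35 ± 0.826 RPKM (1.09 ± 0.09), BHLHA15 from 10.0 ± 1.19 to 20.7 ± 0.495 (1.02 ± 0.08) and CYP1A1, a target of the aryl hydrocarbon receptor, from 6.54 ± 0.378 to 13.7 ± 0.352 (1.01 ± 0.05). ALB was higher as well (1.18 ± 0.32) and so was RBP4 (1.38 ± 0.42), the carrier of retinol in plasma, whose siSGK3 replicate 3 lay among the siAREG libraries. ALB stood at 0.15 with a term for liver transcripts (limma adjusted p = 0.526) and lost its call without siSGK3 replicate 1 (0.93, 0.0502) or 2 (0.92, 0.0632). ZBTB8OS (-1.25 ± 0.07) and MGP, which encodes matrix Gla protein (-1.02 ± 0.07; 5.32 ± 0.0792 and 2.38 ± 0.223 RPKM), were lower in siAREG, as were the short RNA genes SNORD34 (-1.26 ± 0.30), MIR3648 (-0.94 ± 0.09) and MIR3687 (-1.38 ± 0.40). The MIR3687 call ended without siSGK3 replicate 2 (-1.19, limma adjusted p = 0.0807), and its change was -0.80 without siAREG replicate 3. With a term for liver transcripts it stood at -0.92 (0.275). Without the filter the calls of MIR3687 (0.0891) and ALB (0.0632) ended too. Of genes called in both knockdowns in the same direction, 3304 were further from siNC in siAREG by this test and 114 in siSGK3.

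Camera called 11 lists. All 25 interferon genes were higher in siAREG (median 0.53, camera adjusted p = 3.45e-12; 0.222 with an estimated correlation), as in IFIT2 (0.81 ± 0.06) and OASL (0.79 ± 0.07). ER chaperones were higher in 23 and lower in 1 of 25, or 24 and 1 adjusted over the list alone (median 0.33, 1.03e-09; 0.222), and ATF4 targets higher in 21 and lower in 0 of 25, or 23 and 0 (median 0.29, 2.85e-08; 0.222), with DNAJB9 at 0.77 ± 0.03 and WARS at 0.44 ± 0.03. Estrogen receptor targets were lower in 23 and higher in 2 of 34 (median -0.29, 5.06e-11; 0.0834), led by PDZK1 (-0.77 ± 0.03) and GREB1 (-0.48 ± 0.03), and ESR1 itself was lower (-0.40 ± 0.04). S phase genes were lower in 19 of 25 (median -0.18, 2.85e-08; 0.0834) and G2 genes in 17 of 26 (median -0.12, 2.12e-07; 0.210), or 20 and 18 adjusted over the list alone. Luminal genes were lower in 10 of 21 (median -0.07, 0.00131; 0.222), cholesterol genes in 12 of 24 (median -0.07, 0.00272; 0.381) and ribosomal protein genes in 20 of 38, or 23 adjusted over the list alone (median -0.09, 2.12e-07; 0.488). The luminal (0.0989), ribosomal (0.842) and androgen receptor (0.0953) lists lost their call after quantile normalization, and the androgen receptor list also after median ratio scaling (0.0561). The p53 list (12 higher and 1 lower of 21, 0.0409; 0.381) and the androgen receptor list (2 higher and 4 lower of 12, 0.0389; 0.222) also passed. They had 12 and 2, and 2 and 7, adjusted over the list alone. Both lost the call when siSGK3 replicate 3 was left out (0.0741 and 0.0569) or either of siNC replicates 1 and 2. The p53 call also ended among genes at RPKM 5 or more (0.0545), with 2 groups in the fit (0.0560), and without siSGK3 replicate 1 (0.0650) or siAREG replicate 3 (0.0840), and the androgen receptor call without siNC replicate 3 (0.0702). The second p in each bracket is that with an estimated correlation. The other 11 lists were not called (camera adjusted p from 0.189 to 0.988). Genes higher and lower, with the camera adjusted p, numbered 1 and 2 of 6 for the basal and stromal list (0.835), 2 and 1 of 12 for the ERBB list (0.861) and 4 and 4 of 20 for the ERK list (0.199). There were 6 and 2 of 17 for the ER calcium list (0.404), 3 and 1 of 13 for the AKT and SGK list (0.404) and 7 and 3 of 18 for the FOXO list (0.404). There were 5 and 2 of 14 for the BCL2 list (0.413), 5 and 10 of 22 for the hypoxia list (0.189) and 8 and 7 of 21 for the lysosome list (0.404). There were 3 and 1 of 12 for the histone list (0.988) and 2 and 0 of 15 for the small RNA pathway list (0.487). Adjusted over the list alone the counts became 7 and 10 for the hypoxia list and 1 and 0 for the small RNA pathway list, and were unchanged for the other lists not called.

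Of all calls in this comparison 60.5% were higher; quantile normalization turned this to 48.1%, so which direction held more genes depends on the scaling. Within the split by liver transcripts the comparison has 1 siSGK3 library on the side of the siAREG libraries. A fit with a term for that split called 1402 genes higher and 1091 lower and kept all 11 lists.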

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

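The splits of libraries, the comparison of the knockdowns, the rule that named the most opposite genes and the fit without the filter were planned before the data were examined. The plasma proteins tested in that fit were picked afterwards. Apart from the splits, every test of an explanation in this section was also chosen afterwards.

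These values drew a further look because the gene was called in opposite directions by the knockdowns. The differences siAREG minus siSGK3 were ARL1 0.74 ± 0.03, ELOVL7 0.68 ± 0.05, TMEM167B 0.60 ± 0.04, ZBTB41 0.55 ± 0.05 and ZNF746 0.55 ± 0.05 (log2 fold change ± SE, n = 3 per group). The genes were picked for the largest such differences, so these values are no separate test of them. TMEM167B in siSGK3 and ZNF746 in siAREG are small changes whose calls ended in several settings. Other values were looked at because the genes lay below the filter and so outside the main results: the plasma proteins TF at 0.975, AHSG at 0.939, AFP at 0.610 and APOA1 at 0.402 mean RPKM in siSGK3 replicate 3 and siAREG replicates 1 to 3. In the fit without the filter all 4 passed in siAREG against siNC (limma adjusted p = 0.00538, 0.0139, 0.00569 and 0.00697) and none in siSGK3 against siNC (lowest 0.287). These plasma proteins were picked from markers higher in siSGK3 replicate 3 and all siAREG libraries than in every other library. Their passing in siAREG was therefore built in and is no further evidence.

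Regrouping the 6 libraries of a comparison gives 10 splits, too few for a share under 0.05. The real split called 7094, 8685 and 4958 genes in siSGK3 against siNC, siAREG against siNC and siAREG against siSGK3, and the highest other split called 1, 0 and 0, so 1, 1 and 1 of 10 splits called as many as the real one.

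Liver transcripts in siSGK3 replicate 3 and the siAREG libraries may come from RNA or reads of a liver-derived source, as 47.4% of measured liver markers lay higher in all 4 than in all 5 others, against 9.17% of all genes with a value and 0.794% in a random order. That share was below the level set for this explanation, so it stays open. The split was defined by ALB, itself among these markers, after liver transcripts had been seen. The share in a random order is therefore too low a reference. SGK3 was as low in siSGK3 replicates 1 and 2 as in replicate 3 (3.42 ± 0.0772 RPKM over all 3). Of all 38 measured markers, replicates 1 and 2 lay above all siNC libraries in 3, or 7.89%. Many markers, such as AFP, APOB and RBP4, were at 0 in all of these libraries, so a random order gives no valid reference. That so few markers rose argues against a response to SGK3 knockdown alone as the cause in siSGK3 replicate 3. The mean of replicates 1 and 2 reached 0.5 of replicate 3 in 11.1% of the 18 separating markers. Those markers were picked for lying higher in replicate 3, so that share cannot decide. RBP4, APOA2, AHSG and AFP, at 0 in replicates 1 and 2, are among the markers picked this way. A response to AREG knockdown stays open for the siAREG libraries, as all 3 lay above all siNC libraries in 50% of all measured markers and the group is confounded with the split. Such a response would not account for siSGK3 replicate 3, where AREG was 78.4 RPKM, against 83.0 ± 2.48 in siNC. The 4 libraries have adjoining column numbers, and their handling is not given in the sources used here.

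The shared response may reflect a reaction to the pools apart from their targets, since 25 of 25 interferon genes rose in both. Loss of targets that act on the same process is another possible cause. The covariance exceeded the simulated one by 0.131, but any shared cause would raise it, so it favours neither of these causes. Both stay open, because the control siRNA came from a different supplier than both pools. An equal effect of supplier alone would leave the pools alike, yet 51.0% of shared genes also differed in the same direction between siAREG and siSGK3. An unequal effect of supplier, or one added to that of knockdown, cannot be told apart from knockdown in this design. Deeper sequencing of the knockdown libraries would act on low genes, yet 61.7% of genes at RPKM 5 or more were called in both in the same direction, against 53.9% of all genes.

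The fall of SGK3 in siAREG could come from siSGK3 material mixed into those libraries, but the share needed would bring AREG to 46.0 RPKM and it was 22.1 ± 4.04 (SD, n = 3). An action of the siAREG pool on shared exons stays open. C8orf44-SGK3 stood at 95.0% of siNC in siAREG (log2 fold change -0.04 ± 0.11), while its fall in siSGK3 was seen (-0.83 ± 0.11). It lay below the filter, and how its reads were divided from those of SGK3 is not given, so these values do not decide. A link to the fall of ESR1 stays open too, since 35.3% of the 34 measured estrogen receptor targets fell as far as SGK3 or further.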

How the results depend on the processing

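Most tests of named genes and of lists held across settings. Of gene tests 2562 stayed the same, 2 grew stronger and 69 weaker. Named genes were mostly picked for large changes or low p-values in these data, so they do not stand for all called genes. Of list tests 1302 stayed the same, 36 grew stronger, 43 weaker and 2 reversed. A test also counts as the same where it was called in neither setting. Among list tests, 25 of the stronger and 1 of the reversed are fry, a test against no change and not against other genes. With a least change of 1.5-fold, 594 genes were higher and 115 lower in siSGK3 than in siNC, 1228 and 444 in siAREG than in siNC, and 81 and 26 in siAREG than in siSGK3, with 659 shared in the same direction and 0 opposite. A term for liver transcripts left 1402 higher and 1091 lower genes in siAREG against siSGK3 and 13 opposite genes. Camera with an estimated correlation called 0, 0 and 0 lists in the 3 comparisons (4, 4 and 3 at an unadjusted p under 0.05). Fry called 16, 22 and 14, which does not bear on whether lists differ from other genes. The ribosomal protein list in siAREG against siNC reversed after quantile normalization (adjusted p = 0.347); the cause was not tested. The AKT and SGK list in that comparison has the opposite sign in fry (0.0411), which tests another question; the cause was not tested. A replicate block gave 3329 and 3636, 4466 and 4170, and 2925 and 1890 genes higher and lower in the same order, with 6393 shared, and ended the calls of TMEM167B in siSGK3 (0.0681) and of the p53 list (0.0548).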

Other observations

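Genes of interferons, chemokines and other cytokines were mostly higher in both knockdowns. Of 10 measured, limma called 8 higher and 0 lower in siSGK3 and 10 higher and 0 lower in siAREG (median log2 fold change 0.80 in siSGK3 and 1.62 in siAREG, camera adjusted p = 0.000172 and 3.73e-05, and 0.0478 and 0.0355 with an estimated correlation). IFNB1, which encodes interferon beta, changed by 1.00 ± 0.07 in siSGK3 and 2.01 ± 0.07 in siAREG against siNC, the chemokine gene CXCL10 by 0.84 ± 0.09 and 1.78 ± 0.09, and CCL5 by 0.44 ± 0.07 and 1.36 ± 0.07. IFNL3 did not pass in siSGK3 (-0.13 ± 0.15, limma adjusted p = 0.485). Genes of MHC class I antigen presentation, which interferons induce, were 12 higher and 0 lower in siSGK3 and 13 higher and 0 lower in siAREG of 14 (median log2 fold change 0.32 in siSGK3 and 0.66 in siAREG, camera adjusted p = 8.45e-05 and 8.48e-06, and 0.0982 and 0.0696 with an estimated correlation), for example PSMB9 (0.68 ± 0.11 and 1.56 ± 0.11), a subunit of the immunoproteasome, HLA-B (0.46 ± 0.06 and 0.96 ± 0.06) and B2M (0.29 ± 0.04 and 0.63 ± 0.04); HLA genes are alike and may share reads.

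Heat shock chaperones of the cytosol and mitochondria mostly fell while those of the ER rose. Heat shock chaperone genes were 2 higher and 22 lower in siSGK3 and 1 higher and 21 lower in siAREG of 24 (median log2 fold change -0.30 in siSGK3 and -0.47 in siAREG, camera adjusted p = 9.79e-08 and 4.46e-08, and 0.0478 and 0.0435 with an estimated correlation). HSP90AA1 changed by -0.59 ± 0.03 in siSGK3 and -0.96 ± 0.03 in siAREG, HSPA8 by -0.59 ± 0.02 and -0.95 ± 0.02, and the mitochondrial chaperone HSPA9 rose (0.22 ± 0.03 and 0.34 ± 0.03). Genes of COPII vesicles, which carry proteins out of the ER, were 15 higher and 1 lower in siSGK3 and 17 higher and 0 lower in siAREG of 17 (median log2 fold change 0.38 in siSGK3 and 0.59 in siAREG, camera adjusted p = 6.55e-07 and 1.25e-07, and 0.0982 and 0.0696 with an estimated correlation), with SEC24D (1.32 ± 0.04 and 1.86 ± 0.04), SEC24A (1.45 ± 0.04 and 1.74 ± 0.04) and SEC31A (0.70 ± 0.03 and 1.10 ± 0.03), and SAR1A differed in direction (-0.16 ± 0.03 and 0.21 ± 0.03). These 4 lists were chosen after the data were seen and were adjusted over themselves alone, so their p-values are too small to an unknown extent. The liver transcripts were in all siAREG libraries and in siSGK3 replicate 3, and near 0 in siNC.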
